A study of Mus musculus with 12 samples.

How the data were processed

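RNA from 12 mouse tissue pieces was measured on Illumina single-colour bead arrays with biotin-labelled cRNA, 1 array per piece. The labels name 5 normal tongues of control mice given DMSO and 7 tongue tumours of mice given 4NQO (4-nitroquinoline 1-oxide, a DNA-damaging carcinogen) at 200 µg/mL with arecoline (the main alkaloid of areca nut) at 500 µg/mL. Treatment lasted 8 weeks and was followed by a rest of 20 weeks, and the age given for the B6 mice is 8 months. Separate animals are not stated for the pieces, so each p-value measures a difference against the spread between pieces.

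The values used were those deposited by the authors on a log2 scale, 1 column per array for 25697 probes. The base was inferred from the range of the values, which a 16-bit scanner can give only in base 2. Every array had a median of 6.56 while its quartiles differed from those of the other arrays, so the authors' values had been scaled to a common median without a quantile step. No values near 0 were present, hence no sign of a background subtraction. BeadStudio and Partek 6.6 are named in the submitters' processing notes, without their roles. A second table of signals and detection p-values was not used here, because the names of its 24 columns of per-sample values match no sample label. The analysis laid out before the data were examined would have used that table's detection p-values, with neqc for background correction and the slide as a block where headers gave one, and its stated substitute for a table without them was used instead.

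The deposited values were returned to the linear scale, corrected for background with normexp at an offset of 50, quantile normalised and expressed in log2. The background threshold of each array was set at the mode of its deposited values plus 1.64 standard deviations of the side below the mode, which leaves a tail of 5%. A probe was kept when it lay above this threshold on at least 5 arrays, which held for 15699 probes (61.1%). Between 14677 and 15418 probes per array were above background, and the number of arrays limits the precision of every value. Probes were assigned to genes through the array's annotation, with 23978 probes carrying 1 symbol and 1719 carrying none. Of these, 23962 matched a gene identifier in the RefSeq table of the GRCm38.p6 assembly, which served for gene names only. A gene with several probes was represented by the probe with the highest mean signal, which gave 10786 genes.

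Tumours were compared with normal tongue by limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the probes kept and a threshold of 0.05. Fold changes are tumour relative to normal. Where no array of a group lay above background, the fold was computed against the background threshold and is given as a lower bound. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

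All gene lists of the comparison, 29 in number, were fixed before the data were examined. They cover skeletal muscle contraction, mitochondrial respiration, fatty acid oxidation and myokine regulators, muscle stem cells and regeneration, basal squamous epithelium, stress and wound keratins, keratinocyte differentiation and cornified envelope, tongue papilla and hard keratins, cell cycle and mitosis, DNA replication and repair, fibroblast matrix, matrix proteolysis and invasion, regulators of epithelial-mesenchymal transition, hypoxia and glycolysis, T and NK cells, B and plasma cells, macrophages and dendritic cells, neutrophils and acute inflammation, interferon response, mast cells, endothelium, adipocytes, nerve and Schwann cells, salivary gland, erythrocytes and blood, p53 targets and DNA damage, NRF2 and xenobiotic metabolism, oral squamous carcinoma drivers, and reference genes. Each list was tested with camera at a preset correlation between genes of 0.01, adjusted over the 29 lists. Beside it stand camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. A list score is the mean log2 signal of the list's measured genes on an array. A further 12 lists were written after the first results were seen and before their own values were seen, and they are adjusted among themselves.

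Genes named were chosen by a rule fixed before the data were examined. It took the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, passing over unnamed, predicted and clone-named genes, the members of each list with the largest changes past the threshold (up to 4 per list), and measured members of the lists of carcinoma drivers, stress keratins and reference genes. Genes named outside this rule are said to have been chosen after their values were seen.

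In the 7 tumours, 6 pairs of list scores fixed before the data were examined were correlated (Pearson and Spearman, two-sided exact permutation tests, Benjamini-Hochberg over the 6 pairs). The workflow was tested on simulated data of 10786 genes, in which 56%, 84%, 96% and 100% of genes changed by log2 0.5, 1, 2 and 3 were recovered. There 8 of 176 calls were false, a raised list was called and 0 of 50 unchanged lists were called. The simulated genes varied independently, with 1 spread for both groups, and the simulated lists were drawn at random. Genes of the real lists vary together, with an estimated correlation of 0.74 for muscle contraction and 0.76 for cell cycle. The simulation therefore does not test the preset correlation of camera.

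Alternatives changed a single choice at a time, except for the deposited values as given and the replicate number as a block. They were no background correction with a constant of 16 added, an offset of 16, centring on the 75th percentile, centring on the median of the reference genes (1 probe per gene), cyclic loess, the deposited values as given, no signal filter, a filter asking for every array of a group, a stricter background tail of 1%, the mean over a gene's probes, eBayes with trend and robust, array weights, an exact rank-sum test, the replicate number as a block, normalisation without the muscle, respiration and fatty acid oxidation lists, and leaving out each array in turn. An alternative without normal 1 and tumour 2 was added after the data were seen. The deposited values as given leave out both the background correction and the quantile step. Tumours 6 and 7 share a number with no normal, so under the block by replicate number they had no part in the change.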

Results

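Gene expression was measured in 5 normal tongues and 7 tongue tumours, with 14677 to 15418 probes above background on each array. The series asks which protein-coding genes differ between oral tumours of carcinogen-treated mice and normal tongue of control mice. Arrays correlated at r = 0.973 to 0.996 among normals, 0.925 to 0.984 among tumours and 0.804 to 0.911 between the groups, across genes. The first principal component held 73.4% of the variance and the second 8.97%.

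Of named genes whose groups did not overlap, Sprr2d and S100a9 rose most in the tumours, and Myh4 and Ckm fell most. Sprr2d (probe ILMN_2626516), a small proline-rich protein of the cornified envelope, rose 358-fold (log2 8.48, SE 0.13), from 6.48 ± 0.17 (SD, n = 5) to 14.97 ± 0.27 (SD, n = 7). S100a9 (probe ILMN_2803674), a subunit of the neutrophil protein calprotectin, rose by log2 7.39 (SE 0.36), and S100a8, the other subunit, rose by 6.55 (SE 0.34). Myh4 (probe ILMN_1241214), a fast myosin heavy chain, fell by log2 5.97 (SE 0.77), from 13.79 ± 0.16 (SD, n = 5) to 7.82 ± 1.90 (SD, n = 7). Ckm, the muscle creatine kinase, fell by 5.82 (SE 0.92).

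Of 10786 genes, limma called 3506 higher and 2541 lower in tumours, and 4739 were not called. At least 2-fold changes were called for 666 genes higher and 995 lower. The values of the 2 groups did not overlap for 4079 of the 10786 genes, where chance gives 0.253%. Which direction held more genes depended on the scaling, since 58.0% of the called genes were higher here, 46.3% under cyclic loess (2642 higher, 3069 lower) and 6.14% under centring on the reference genes (494 higher, 7553 lower). Under the quantile step the reference genes were themselves higher in the tumours. Centring on them therefore lowered the median change of all genes from 0.07 to −0.65, and 762 of the genes called higher were then called lower. Whether the reference genes rose or the scaling raised them was not tested. Of 1754 called genes with another probe kept, 538 had a probe that was not called and 27 a probe called in the opposite direction.

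Among the 10 largest rises of named genes without overlap were Sprr2e (at least 91.2-fold), Sprr2f (at least 81.2-fold), Sprr2g (log2 5.89) and Sprr2i (log2 5.24). The Sprr2 genes are close paralogs, so probes may not tell them apart. The others were the collagenase Mmp13 (log2 4.91), AA467197 (4.84) and Saa3, an acute-phase apolipoprotein (4.69). Mmp13 was above background in 1 of 5 normals, and had a change of 2.25 with the mean over its probes. The 10 largest such falls held the muscle genes Actc1 (log2 −5.73), Ckmt2 (−5.69), Cox7a1 (−5.58), Eno3 (−5.28) and Cox8b (−5.21). They also held the keratin-associated proteins Krtap13 (−5.69) and Krtap4-1 (−5.54) and the lysozyme-like Lyg1 (−5.36). None of these 20 largest changes turned direction under any scaling, which their size made all but certain.

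Muscle genes fell in the tumours. Of 25 measured genes of skeletal muscle contraction, 23 fell and 2 were not called (24 fell adjusted over the list alone), with a median log2 change of −3.67. Among them were Tcap (−5.09) and Myoz1 (−4.91), both of the sarcomere's Z-disc. The camera test gave an adjusted p = 1.05e-08 and an adjusted p = 0.314 with an estimated correlation. Genes of muscle stem cells and regeneration fell in 5 of 7 cases (also 5 adjusted over the list alone; median −0.80, −0.45 to −0.37 without any 1 of the 5 normals, −0.26 with no signal filter and −0.42 with the mean over probes, camera adjusted p = 0.00118, adjusted p = 0.105 with an estimated correlation). Examples were Myf6 (−3.36), a myogenic regulator, and Chrna1 (−2.27), a subunit of the muscle acetylcholine receptor. The muscle score was 13.02 ± 0.16 (SD, n = 5) in normal tongue and 9.52 ± 1.31 (SD, n = 7) in tumours, where tumour 2 had the highest value at 11.91.

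Genes of mitochondrial energy metabolism fell alongside. In mitochondrial respiration 23 of 24 genes fell (also 23 adjusted over the list alone), with a median of −1.33. Its camera adjusted p was 3.58e-13, with an adjusted p = 0.105 with an estimated correlation. The largest falls were in Cox7a1, Cox8b and Cox6a2 (−4.67), the muscle forms of cytochrome oxidase subunits, and Idh3a (−2.60), of the citric acid cycle. Fatty acid oxidation and myokine regulators fell in 14 of 14 genes (14 adjusted over the list alone; median −2.16, camera adjusted p = 3.49e-09, adjusted p = 0.193 with an estimated correlation). Fabp3 (−4.81) and Cpt1b (−4.19) handle fatty acids in muscle, Lpl (−4.22) releases them from lipoproteins and Pdk4 (−3.50) restrains glucose oxidation. Muscle contraction genes fell in the same arrays.

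**Figure D1:**
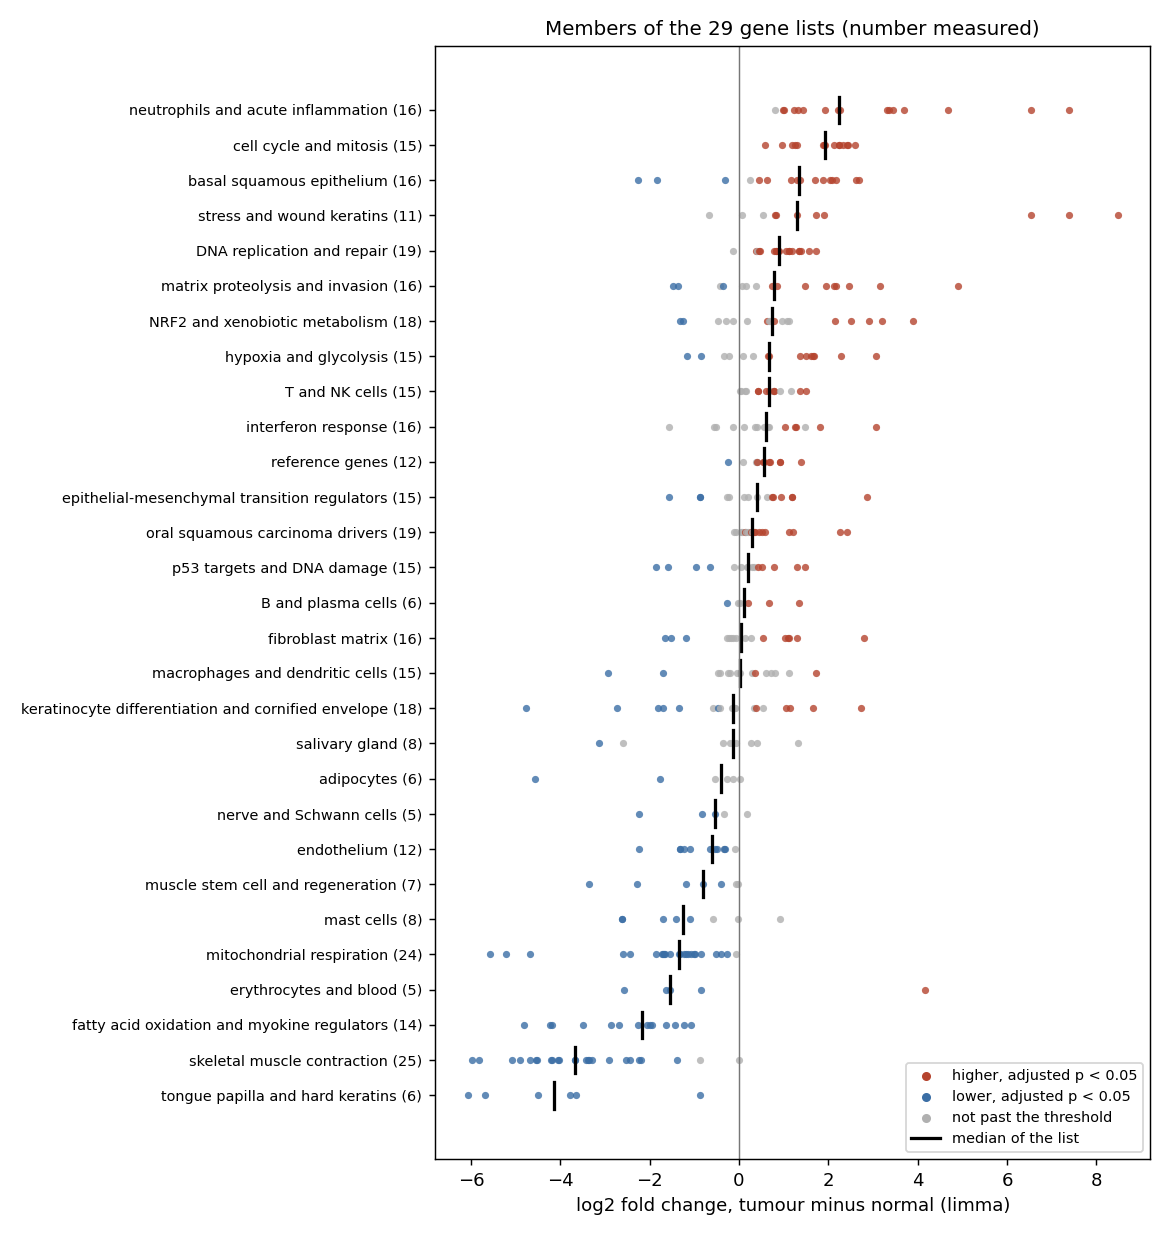
Log2 fold change of tumour relative to normal tongue (x axis, limma) for each measured member of the 29 gene lists (y axis, number measured in brackets), with a bar at the list median. Red points are genes called higher, blue points genes called lower and grey points genes not called. Muscle contraction had 23 of 25 members lower and the cell cycle 15 of 15 higher. Medians near 0 change sign under other scalings.

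Squamous epithelium changed in both directions. Stress and wound keratins and their companions rose in 8 of 11 genes, with 0 falling (8 adjusted over the list alone; median 1.30). The camera adjusted p was 1.71e-04, and the adjusted p = 0.0706 with an estimated correlation. Keratins of wounded epidermis were among them, Krt17 (log2 1.90), Krt6a (1.71), Krt6b (0.84, or 1.87 with the mean over its probes) and Krt16 (0.81), with the envelope precursor Sprr1b (1.30). Defb4, a beta-defensin, had a log2 change of −0.68 and was not called, but was called lower under cyclic loess (−0.99), with array weights (−0.66) and with the replicate number as a block (−0.43), and had −0.36, not called, without tumour 7. Basal squamous epithelium had 12 genes higher and 3 lower of 16 (the same counts adjusted over the list alone; median 1.34, camera adjusted p = 0.0063, adjusted p = 0.295 with an estimated correlation). The desmosomal cadherin Dsg3 (2.69), P-cadherin Cdh3 (2.62, or 1.70 with the mean over its probes) and the laminin chain Lamb3 (2.17) rose, while the basal keratin Krt15 (−2.25) fell.

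Differentiation genes split. Of 18 genes of keratinocyte differentiation and cornified envelope, 5 rose, 6 fell and 7 were not called (6 and 6 adjusted over the list alone), and the list was not called (median −0.12, camera adjusted p = 0.688; −0.32 under cyclic loess, and −0.22 to 0.01 over the leave-outs). Krt76 (−4.77), a keratin of oral mucosa, Krt24 (−2.73) and Krt4 (−1.81, or −1.14 with the replicate number as a block), a keratin of the tongue surface, fell, and the protease Klk6 rose at least 4.95-fold. Hard keratins of the tongue papillae fell in 6 of 6 genes (6 adjusted over the list alone; median −4.14), among them Krt34 (−6.08) and Krt84 (−3.78). The camera adjusted p was 9.40e-04, and the adjusted p = 0.295 with an estimated correlation. Tumour 4 had a hard keratin score of 10.60 where the other tumours had at most 8.15.

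Proliferation genes rose. In cell cycle and mitosis 15 of 15 genes rose (15 adjusted over the list alone), with a median of 1.93. Examples were Cenpa (2.61), a centromeric histone, Cdc20 (2.44), which activates the anaphase-promoting complex, Prc1 (2.42), which bundles spindle microtubules, and the mitotic kinase Plk1 (2.32). The camera test gave an adjusted p = 7.48e-08, and an adjusted p = 0.295 with an estimated correlation. DNA replication and repair rose in 17 of 19 genes (18 adjusted over the list alone; median 0.90, camera adjusted p = 1.01e-04, adjusted p = 0.421 with an estimated correlation). Mcm5 (1.72), of the replicative helicase, and Uhrf1 (1.56), which maintains DNA methylation, were among them.

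**Figure D2:**
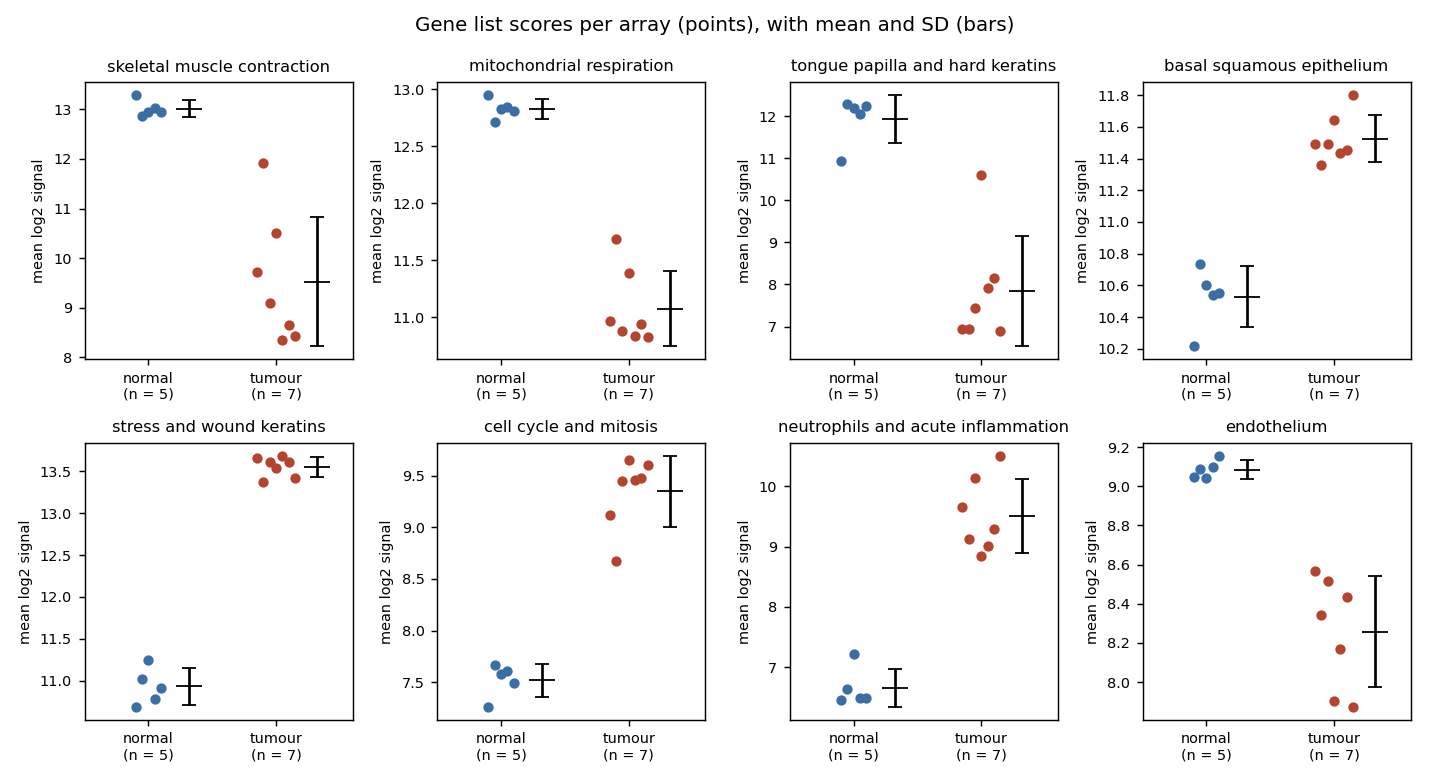
Scores of 8 gene lists on each array (y axis, mean log2 signal of the list's measured genes) in normal tongue (blue, n = 5) and tumours (red, n = 7), with the mean and SD as bars. The muscle score averages 13.02 in normal tongue and 9.52 in tumours, and the cell cycle score 7.52 and 9.35.

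Stromal lists held changes in both directions and were not called. Fibroblast matrix had 6 genes higher, 3 lower and 7 not called (6 and 3 adjusted over the list alone; median 0.04, camera adjusted p = 0.997). This median turned to −0.02, −0.68 and −0.04 under centring on the 75th percentile, centring on reference genes and cyclic loess, ranged from −0.02 to 0.14 over the leave-outs, and camera ranked the list downward while its mean was 0.19. Tnc (2.81, or 1.69 with the mean over its probes), a matrix protein of wounds, and Col1a1 (1.30) rose, and the proteoglycans Lum (−1.66) and Dcn (−1.53) fell. Matrix proteolysis and invasion had 9 genes higher and 3 lower of 16 (9 and 3 adjusted over the list alone; median 0.80, camera adjusted p = 0.0813), with Mmp10 at least 7.32-fold higher, Plau (2.47), the urokinase, and Mmp3 (2.17). Regulators of epithelial-mesenchymal transition had 6 higher and 3 lower of 15 (7 and 4 adjusted over the list alone; median 0.39, or 0.18 under cyclic loess, camera adjusted p = 0.434). Inhba (2.86), an activin subunit, and Tgfbi (1.19) rose and the transcription factor Zeb1 (−1.57) fell. Hypoxia and glycolysis had 9 higher and 2 lower of 15 (9 and 2 adjusted over the list alone; median 0.68, or 0.34 under cyclic loess, camera adjusted p = 0.0899), with the glucose transporter Slc2a1 (3.07) and Hif1a (2.29) higher.

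Neutrophil and acute inflammation genes rose. Here 15 of 16 genes were higher (15 adjusted over the list alone), with a median of 2.24, or 1.98 with genes below background in normal tongue placed at their bound. Next to S100a9, S100a8 and Saa3 stood the chemokine Ccl4, at least 9.64-fold higher. The camera adjusted p was 8.78e-06, and the adjusted p = 0.295 with an estimated correlation. S100a8 and S100a9 also belong to the list of stress keratins. Genes of T and NK cells rose in 8 of 15 cases (8 adjusted over the list alone; median 0.68, or 0.44 with no signal filter, camera adjusted p = 0.0483, adjusted p = 0.543 with an estimated correlation). The T cell receptor chains Cd3g (2.83-fold, above background in 1 of 5 normals) and Cd3d (at least 2.29-fold) were higher. The T and NK cell score was 7.76 to 7.92 in tumours 1 to 3 and 6.83 to 7.23 in tumours 4 to 7, against 6.71 to 6.81 in normals. That list's call was lost without normal 1, 2, 3 or 5 or tumour 1, 2 or 3 (medians 0.61 to 0.77 over all 12 leave-outs), and under 3 other treatments of the signal and 2 other filters (medians 0.61 to 0.78), and its median turned to −0.05 under centring on the reference genes.

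Of the other immune lists only that of mast cells was called. B and plasma cells had 3 genes higher and 1 lower of 6 (3 and 1 adjusted over the list alone; median 0.12, or 0.05 with genes below background in normal tongue at their bound, −0.005 with no signal filter and −0.01 to 0.21 over the leave-outs, camera adjusted p = 0.633), with Sdc1 at 1.34. Macrophages and dendritic cells had 2 higher, 2 lower and 11 not called (1 and 2 adjusted over the list alone; median 0.01, mean −0.02 and camera's direction downward, camera adjusted p = 0.789), and the median turned to −0.03, −0.70 and −0.15 under centring on the 75th percentile, centring on reference genes and cyclic loess and ranged from −0.18 to 0.16 over the leave-outs. The macrophage score was 9.8 to 10.5 in tumours 1 to 3 and 8.9 to 9.2 in tumours 4 to 7, against 9.3 to 9.7 in normals. A median near 0 thus joins tumours above and below all normals. The scavenger receptor Cd163 (−2.93) and the mannose receptor Mrc1 (−1.71) fell, and the lipopolysaccharide receptor Cd14 (1.73) rose. The interferon response had 5 of 16 genes higher (1 adjusted over the list alone; median 0.61, camera adjusted p = 0.527), with Tap1 at 1.26. Its median was 0.25 without tumour 3, 0.38 with no signal filter and 0.96 with the replicate number as a block. Cxcl9 rose by log2 3.08 (SE 1.10, adjusted p = 0.0299), and its call was lost when any of 6 arrays was left out (normals 1 to 4, tumours 1 and 2; log2 2.48 to 3.67 over all 12). Mast cell genes fell in 5 of 8 cases (5 adjusted over the list alone; median −1.26, camera adjusted p = 0.0288, adjusted p = 0.479 with an estimated correlation), among them the proteases Mcpt4 (−2.62) and Cpa3 (−2.61). The mast cell call was lost under cyclic loess (median −1.33) and with the replicate number as a block (−1.15).

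Endothelial genes fell in 10 of 12 cases (10 adjusted over the list alone; median −0.59). The lymphatic receptor Lyve1 (−2.25) and the VEGF receptor Flt1 (−1.31) were among them. The camera adjusted p was 2.85e-04, and the adjusted p = 0.314 with an estimated correlation. Adipocytes had 2 of 6 genes lower (2 adjusted over the list alone; median −0.40, or −0.14 with no signal filter and −0.003 without normal 1, camera adjusted p = 0.0966), with the lipid droplet protein Plin4 at −4.56. Nerve and Schwann cells had 3 of 5 lower (4 adjusted over the list alone; median −0.53, or −0.02 with no signal filter, camera adjusted p = 0.0677), with the myelin protein Pmp22 at −2.25. Erythrocytes and blood had 4 genes lower and 1 higher of 5 (4 and 1 adjusted over the list alone; median −1.54, mean −0.49, camera adjusted p = 0.0622; called with no signal filter at a median of −0.49). The haemoglobin chain Hba-a1 (−2.58) fell and the platelet chemokine Ppbp rose at least 14.4-fold.

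Salivary gland genes were not called as a list (1 of 8 lower, 1 adjusted over the list alone; median −0.13, turning to 0.76 without normal 1, camera adjusted p = 0.658). Their score was 11.09 on normal 1 and 9.90 on tumour 2, against 6.44 to 7.11 on the other arrays. Amylase, Amy1 (−3.13), was the gene called lower, with 14.21 on normal 1 and at most 9.04 on the other normals, and with a change of −2.01 without normal 1. Without these 2 arrays 3486 genes were higher and 2312 lower, and 672 and 965 changed at least 2-fold.

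Of the genes of known pathways, p53 targets and DNA damage had 5 higher and 4 lower of 15 (5 and 4 adjusted over the list alone; median 0.21, or 0.03 under cyclic loess and 0.13 with the mean over probes, camera adjusted p = 0.818). Plk2 (1.49) rose, and Ccng1 (−1.86, or −1.17 with the mean over its probes) and Gadd45a (−1.59) fell. NRF2 and xenobiotic metabolism had 7 higher and 2 lower of 18 (7 and 2 adjusted over the list alone; median 0.74, camera adjusted p = 0.0873), with the reductase Akr1b8 (3.90), the cystine transporter Slc7a11 (3.20) and the glutathione synthesis gene Gclm (2.91) higher. Tumour 6 had the highest NRF2 score, 11.98 against 10.03 to 10.94 in the other tumours.

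Carcinoma drivers rose in 11 of 19 genes, with 0 falling (11 adjusted over the list alone, median 0.28, or 0.12 under cyclic loess, camera adjusted p = 0.0149, adjusted p = 0.105 with an estimated correlation). This median lay below that of the reference genes (0.55). The list does not separate genes that promote tumours from genes that restrain them, so its rise gives no direction of driver activity. Fscn1 (2.41), which bundles actin, Hbegf (2.26), an EGF receptor ligand, Casp8 (1.21) and Cdkn2b (1.11) rose most. Cdkn2a (0.58, or 1.19 with the mean over its probes), Ccnd1 (0.51) and Myc (0.45) also passed the threshold, and the calls of Ccnd1 under cyclic loess (0.24), of Cdkn2a in the rank-sum test and of Myc with the replicate number as a block (0.31) were lost. Notch1 had a change of 0.28, Sox2 of 0.16 and Egfr of 0.07, none of them called. Under cyclic loess they had 0.11, 0.03 and −0.09, and Egfr turned to −0.003 without normal 1. With the mean over probes Egfr (0.32) and Sox2 (0.18) were called higher, and Sox2 also without normal 4 (0.23). Reference genes rose in 8 of 12 cases and fell in 1 (8 and 1 adjusted over the list alone; median 0.55, or 0.36 under cyclic loess, camera adjusted p = 0.0169, adjusted p = 0.245 with an estimated correlation). B2m (1.39), Rpl13a (0.92), Actb (0.91) and Tbp (0.39) rose, Gapdh (−0.24) fell and Tfrc had a change of 0.39 that was not called. Tfrc was called without tumour 2 (0.49), without tumour 3 (0.46) with the mean over probes (0.44) and with array weights (0.41). Of the other 4 probes of Actb, 2 were called in the opposite direction, and with the mean over its probes Actb had a change of 0.20 that was not called. The call of Gapdh was lost on the deposited values, while under cyclic loess its change was −0.48 and those of Actb and Tbp were 0.60 and 0.25.

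Centring on the reference genes made rises smaller and falls larger. The centring itself places the reference genes near 0, so their change there is not a test of them. List medians that stayed above 0 were those of neutrophils (1.51), cell cycle (1.22), basal epithelium (0.61), stress keratins (0.47), DNA replication (0.21) and matrix proteolysis (0.10, with the call gained). They turned below 0 for T and NK cells (−0.05), carcinoma drivers (−0.39), reference genes (−0.16), epithelial-mesenchymal transition (−0.30), hypoxia (−0.15), interferon (−0.09) and NRF2 (−0.003), which camera placed above the other genes, past the threshold. Also below 0 were p53 targets (−0.46), B cells (−0.63), fibroblast matrix (−0.68), macrophages (−0.70), differentiation (−0.83), salivary gland (−0.88), adipocytes (−1.09), nerve (−1.25) and blood (−2.23), none of them called. Muscle contraction (−4.37), respiration (−2.04), fatty acid oxidation (−2.89), muscle stem cells (−1.53), hard keratins (−4.85) and endothelium (−1.29) stayed called, and mast cells (−1.97) did not.

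Among named genes that centring ended the calls of Krt6b (0.08), Krt16 (0.04), Col1a1 (0.61), Tgfbi (0.40), Cd3g (0.75), Cd3d (0.63), Cxcl9 (2.32), Tap1 (0.53), Cdkn2b (0.44), Actb (0.10), B2m (0.63) and Rpl13a (0.23). Ccnd1 (−0.25), Cdkn2a (−0.13) and Myc (−0.30) turned below 0 and were not called, as was Tfrc (−0.27), while Tbp (−0.31), Egfr (−0.59), Notch1 (−0.39), Sox2 (−0.55) and Defb4 (−1.48) were called lower. Calls that held with values moved by more than 1.5 times were those of Krt17 (1.17), Krt6a (1.01), Sprr1b (0.47), Mcm5 (1.05), Uhrf1 (0.89), Sdc1 (0.67), Cd14 (1.02), Plk2 (0.80), Casp8 (0.52), Dcn (−2.35), Flt1 (−1.98) and Gapdh (−0.98).

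**Figure D3:**
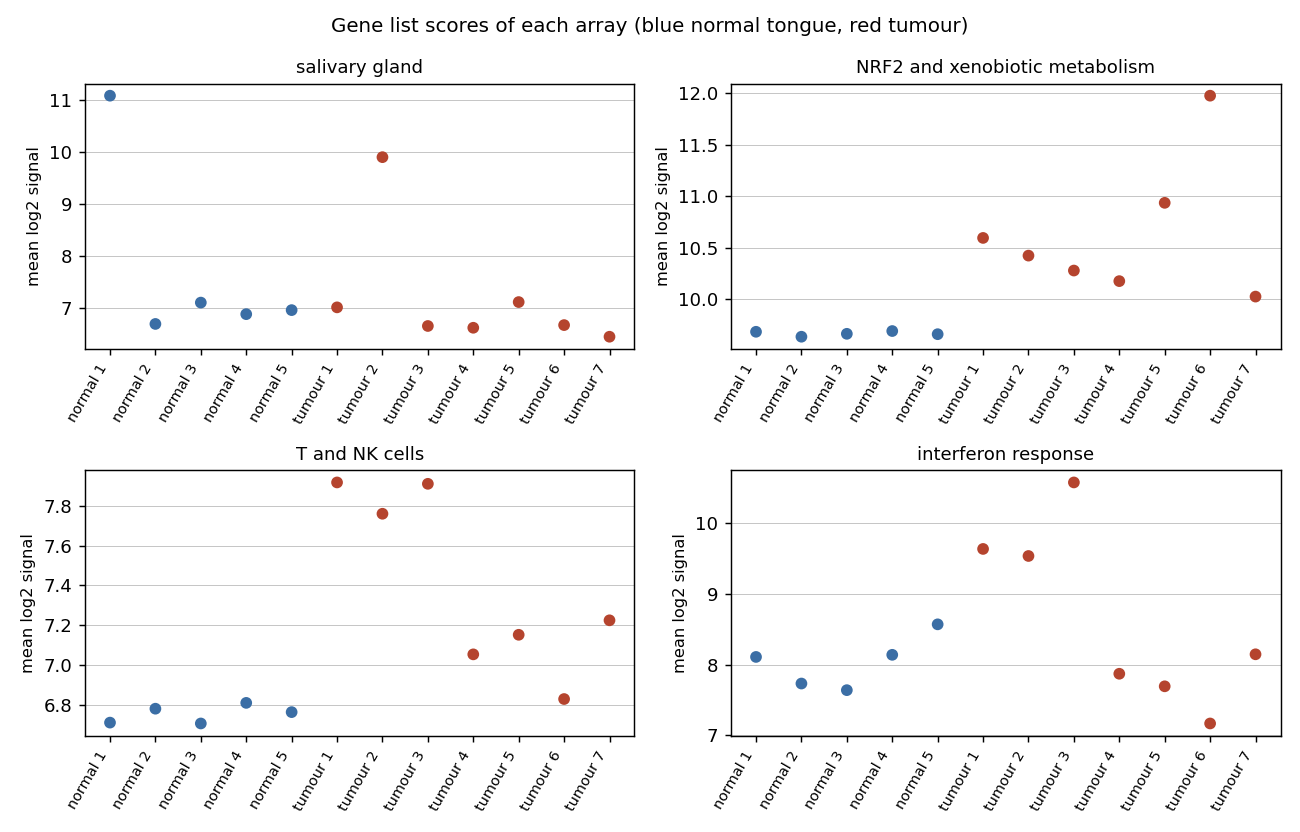
Scores of 4 gene lists (y axis, mean log2 signal of the list's measured genes) on each of the 12 arrays (x axis), normal tongue in blue and tumours in red. The salivary gland score stands at 11.09 on normal 1 and 9.90 on tumour 2, the NRF2 score at 11.98 on tumour 6, and the T and NK cell score at 7.76 to 7.92 on tumours 1 to 3 and 6.83 to 7.23 on tumours 4 to 7.

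Within the 7 tumours, 6 pairs of list scores were compared. Muscle and cell cycle scores had r = −0.717 (exact permutation p = 0.0591, adjusted p = 0.177) and rho = −0.357 (exact p = 0.444, adjusted p = 0.889), with r = −0.886 without tumours 2 and 4. Without tumour 4 alone r was −0.974 and past the threshold, in a range of −0.974 to −0.0597 and of exact adjusted p from 0.0333 to 0.908 over the leave-outs. Muscle and fibroblast matrix scores had r = 0.258 (exact p = 0.584, adjusted p = 0.70) and rho = 0.393 (exact p = 0.396, adjusted p = 0.889), and r = 0.943 (exact p = 0.0167) in the 5 tumours left without tumours 2 and 4, in a range of 0.10 to 0.47 when 1 array was left out. Muscle and basal epithelium scores had r = −0.349 (exact p = 0.444, adjusted p = 0.691) and rho = −0.143 (exact p = 0.783, adjusted p = 0.906), with r = −0.281 without tumours 2 and 4. Its sign turned without tumour 2 alone (0.0943, in a range of −0.531 to 0.0943 over the leave-outs), and under cyclic loess r was −0.0572. Basal epithelium and differentiation scores had r = −0.344 (exact p = 0.461, adjusted p = 0.691) and rho = −0.250 (exact p = 0.595, adjusted p = 0.892). Without tumours 4 and 7 r was 0.499 and without tumour 7 alone 0.638 (−0.689 to 0.638 over the leave-outs), and the sign of r also turned under centring on the 75th percentile and on the deposited values. Stress keratin and neutrophil scores had r = −0.175 (exact p = 0.715, adjusted p = 0.715) and rho = −0.0714 (exact p = 0.906, adjusted p = 0.906), with r = 0.190 without tumours 2 and 7, 0.280 without tumour 7 alone (−0.534 to 0.280 over the leave-outs) and −0.529 on the deposited values. Under centring on the reference genes r was −0.333 for muscle and cell cycle, 0.574 for muscle and fibroblast matrix, 0.688 for muscle and basal epithelium, −0.241 for basal epithelium and differentiation and 0.0757 for stress keratins and neutrophils, none past the threshold. For T and NK cells and the interferon response, tumours 1 to 3 stood apart from tumours 4 to 7 in both scores (interferon 9.53 to 10.57 and 7.17 to 8.14). These clusters are too small for a correlation within each, so the relation of the 2 scores apart from this separation was not tested.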

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

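The tests of array quality and of exchanged labels were chosen only after the result was seen. In 28 of 266 groups, formed by 1 list score or named gene on the normals or on the tumours, a single array stood far from the others of its group by Dixon's test, where chance gives about 1 in 20 groups (13.3 here). Of these, 11 were on normal 1. List scores were tested beside their own genes, so the groups are not independent and a single difference can count several times. All values are log2 signal.

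Salivary gland genes were high in normal 1 (score 11.09) and in tumour 2 (score 9.90), against at most 7.10 in other normals and 7.11 in other tumours. The reference gene score of the 2 arrays differed from the others of its group by at most 0.106. It was taken after the quantile step, which removes differences of scale, so it cannot decide on lower array quality or scaling. The tables argue against an exchange of the 2 labels. The stress keratin score of each array lay at least 2.38 from the mean of the other group and nearer its own. The muscle score of normal 1 (13.29) also lay with the normals, but that of tumour 2 (11.91) lay nearer the normal mean (13.02) than the tumour mean (9.52), as an exchange would have it. A bound on the number of probes above background was dropped from the quality test after normal 1 was found to have the fewest of the normals (14839). Gland tissue in the 2 pieces may have contributed but stays open: over 8 gland genes the excess in the 2 arrays had r = 0.361, between the bounds set before the test, with Dcpp2 (6.39 and 7.62) and Aqp5 (4.36 and 5.18) in excess on both, and Bpifa2 (8.26 and 0.95) and Amy1 (5.63 and 0.84) mainly on normal 1. Of these 4 genes Dcpp2, Aqp5 and Bpifa2 were chosen after their values were seen. The r asks whether the excess runs alike over genes in the 2 arrays, so it cannot decide whether either piece alone held gland tissue. No biological explanation was tested, because the labels put these 2 arrays in no group of their own.

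Normal 1 was also low in the score of keratinocyte differentiation (11.85) and of hard keratins (10.93), in Krt34 (12.60), Krtap13 (12.77), Krtap4-1 (9.64), Lyg1 (14.64), Sprr2i (6.45) and Mcpt4 (8.45), and high in Krt17 (13.63) and Amy1 (14.21). Tumour 4 was high in the hard keratin score (10.60), Krt34 (12.80), Krtap13 (12.66) and Krtap4-1 (9.51). Normal 3 was high in the neutrophil score (7.22) and S100a9 (8.69). Normal 2 was high in Mmp13 (7.26) and Col1a1 (9.97), and normal 5 in Tap1 (7.21). Tumour 7 was low in Defb4 (12.13) and Krt4 (9.84) and high in Hbegf (11.38). Tumour 6 was low in Krt6b (14.73) and high in Akr1b8 (13.22). Tumour 1 was high in Chrna1 (7.84) and tumour 2 low in Cdc20 (9.86).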

How the results depend on the processing

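The alternative without normal 1 and tumour 2, and the other scalings of the added lists, their members and the paralogs, were chosen after seeing the data. The 4 counts of called genes stayed within 1.5 times in 108 recomputed values and left that range only under centring on the reference genes (494 higher and 7553 lower, 205 and 2521 at least 2-fold). Over the leave-outs 3194 to 3673 genes were higher and 2293 to 2606 lower, and 636 to 706 and 955 to 1033 changed at least 2-fold. Of the list medians, 778 recomputed values kept their side of the threshold, 31 lost the call, 22 gained it and 7 turned direction with a call on either side. For named genes these counts were 2856, 24, 12 and 7, and for the added lists 40, 11, 5 and 4. All turns came with centring on the reference genes: T and NK cells −0.053, carcinoma drivers −0.39, reference genes −0.16, epithelial-mesenchymal transition −0.30, hypoxia −0.15, interferon −0.088, NRF2 −0.0027, Ccnd1 −0.25, Cdkn2a −0.13, Myc −0.30, Egfr −0.59, Notch1 −0.39, Sox2 −0.55, Tbp −0.31, ribosomal proteins −0.47, proteasome −0.47, ribosome biogenesis −0.021 and cholesterol synthesis −0.024. There matrix proteolysis (0.10) gained and mast cells (−1.97) lost the call. Medians that were not called changed sign under other settings too. The median change of all genes moved between −0.65 under centring on the reference genes and 0.09 on the deposited values, from 0.07.

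With an estimated correlation in camera every list call was lost, at unchanged medians: muscle contraction −3.67, respiration −1.33, fatty acid oxidation −2.16, muscle stem cells −0.80, basal epithelium 1.34, stress keratins 1.30, hard keratins −4.14, cell cycle 1.93, DNA replication 0.90, T and NK cells 0.68, neutrophils 2.24, mast cells −1.26, endothelium −0.59, carcinoma drivers 0.28 and reference genes 0.55. With fry, which does not compare a list with other genes, calls were gained for matrix proteolysis 0.80, epithelial-mesenchymal transition 0.39, hypoxia 0.68, B and plasma cells 0.12, adipocytes −0.40, nerve −0.53, blood −1.54 and NRF2 0.74. Under cyclic loess matrix proteolysis (0.66) and NRF2 (0.56) gained the call and mast cells (−1.33) lost it. With no signal filter matrix proteolysis (0.74), hypoxia (0.67), blood (−0.49) and NRF2 (0.70) gained it. T and NK cells lost the call without background correction (0.65), under centring on the 75th percentile (0.61), on the deposited values (0.74), with the filter on every array of a group (0.78), with the stricter threshold (0.78) and without normal 1 and tumour 2 (0.67). Nerve gained the call with the mean over probes (−0.83) and without normal 1 and tumour 2 (−0.56), while its median was −0.02, not called, with no signal filter. The cause was not tested for any of these. Of lists not called here, medians near 0 also changed sign without some arrays (differentiation 0.01 without tumour 7, salivary gland 0.76 without normal 1, fibroblast matrix, B cells and macrophages without several), the median of adipocytes was −0.003 without normal 1, and fry pointed upward for differentiation genes.

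Over the leave-outs T and NK cells ranged from 0.61 to 0.77 (call lost in 7 of 12: normals 1, 2, 3 and 5, tumours 1, 2 and 3), matrix proteolysis from 0.72 to 0.86 (gained without tumour 4), nerve from −0.58 to −0.49 (gained without tumour 2 or 7) and blood from −1.61 to −1.41 (gained without normal 2 or tumour 2). The r of muscle and cell cycle scores ranged from −0.974 to −0.0597. For T and NK cell and interferon scores, whose tumours form separate clusters, the test planned over all 7 tumours passed the threshold (exact adjusted p = 0.00833). Over the leave-outs r ranged from 0.957 to 0.986, no longer past the threshold without tumour 2, 5, 6 or 7, and was 0.966 without normal 1 and tumour 2, also not past it. The test stayed past the threshold without tumour 1, 3 or 4, which also leaves 6 tumours. The smaller number of permutations alone therefore does not account for the lost calls.

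The replicate numbers gave no sign of pairing the pieces, as r between a normal and the tumour of the same number ran from −0.371 to 0.0957. This r cannot show whether pieces of the same number share a batch. With the number as a block 3137 genes were higher and 2351 lower, and the calls of mast cells (−1.15) and of Myc (0.31) were lost, that of Defb4 (−0.43) was gained, and Krt4 (−1.14) stayed called. Tumours 6 and 7 share a number with no normal and had no part in these changes. The effect of the block was not tested apart from their loss. The slide as a block was not run, because no slide could be assigned to an array. The offset of 16 stands as the alternative because the substitute analysis uses 50. Low signal limits the folds of 150 genes called higher that were above background on no normal, and of 74 called lower that were above it on no tumour.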

Other observations

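The tests of scaling, of muscle share as the only change and of the tumour 6 scaling were chosen only after the result was seen, and the 12 lists described here were added after the first results, before their own values were seen. Clock genes moved in opposite directions in the tumours. Of 11 measured genes of the circadian clock, 9 fell and 2 rose, with a median log2 change of −0.74 (camera adjusted p = 0.0159, adjusted p = 0.409 with an estimated correlation). The output factor Dbp (−1.52), the repressors Per2 (−1.23), Per1 (−0.80), Per3 (−0.37) and Cry2 (−0.74), and Nr1d1 (−0.65) and Nr1d2 (−0.84) fell, and the activators Clock (1.00) and Arntl (0.76) rose. Under centring on the reference genes the list's call was lost (−1.44), and Arntl (0.03) was not called and Clock (0.33) was. The labels give no time of collection.

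Genes of growth and biosynthesis rose. Amino acid transport and synthesis had 9 of 11 genes higher (median 0.85, camera adjusted p = 0.0122, adjusted p = 0.409 with an estimated correlation), among them asparagine synthetase Asns (1.43) and the transporter Slc7a5 (1.12). Cholesterol synthesis had 8 of 12 higher (median 0.68, camera adjusted p = 0.0122, adjusted p = 0.516 with an estimated correlation), among them squalene epoxidase Sqle (1.25). Ribosome biogenesis had 11 of 14 higher (median 0.65, camera adjusted p = 0.0122, adjusted p = 0.516 with an estimated correlation), among them Nop58 (0.99) and fibrillarin Fbl (0.91). Ribosomal proteins had 12 higher and 1 lower of 17 (median 0.29, camera adjusted p = 0.0166, adjusted p = 0.504 with an estimated correlation), and the proteasome core 10 of 12 higher (median 0.29, camera adjusted p = 0.0159, adjusted p = 0.504 with an estimated correlation). Both of these calls were lost under centring on the reference genes (−0.47 each), cyclic loess (0.03 and 0.02) and the deposited values (0.27 each). Under centring on the reference genes the median of amino acid transport and synthesis was 0.17, and those of cholesterol synthesis and ribosome biogenesis turned to −0.02, each above the −0.65 of all genes and past the threshold of camera; Slc7a5 (0.38), Nop58 (0.32) and Fbl (0.21) were then not called, and Asns (0.74) and Sqle (0.57) were. The 6 other added lists were not called, with camera adjusted p from 0.199 to 0.969: unfolded protein response (5 higher, 3 lower of 13; median 0.30, turning to −0.43 under centring on the reference genes), complement and coagulation (3 lower of 8; −0.60), tight and gap junctions (4 higher, 1 lower of 9; 0.20, turning to −0.50 there), WNT targets and inhibitors (4 higher, 3 lower of 9; −0.03, with a mean of 0.19), YAP targets (1 higher, 3 lower of 9; −0.08) and taste cells (2 lower of 8; 0.00, with a sign that turns with the scaling). The genes named in these paragraphs were chosen after their values were seen.

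Respiration and fatty acid oxidation genes were lower in tumours (medians −1.33 and −2.16). The tables argue against the scaling between arrays, since the highest median of both lists under 4 other scalings was −1.30. Basal epithelium and endothelium scores changed apart by 1.82 (exact permutation p = 0.00126 over 792 splits). This cannot decide whether a lower share of muscle was the only change in tissue makeup, because vessels within muscle would be lost with it. Less skeletal muscle in the tumour pieces may account for part of the fall. Of muscle isoforms 10 of 10 fell (median −4.81). Of these, Cox6a2, Cox7a1, Cox8b, Cpt1b and Fabp3 belong to the lists in question, so their fall was already known. The 9 general paralogs had a median of 0.83, with 7 higher and 1 lower (Cox7a2, −0.83, chosen after its value was seen). Under centring on the reference genes their median was 0.002, with 3 higher and 3 lower. The lower ones there were the cytochrome oxidase paralogs Cox6a1 (−0.49), Cox7a2 (−1.51) and Cox8a (−0.32), chosen after their values were seen. In the main scaling Cox6a1 (0.28) and Cox8a (0.48) were higher, so their direction depends on the scaling. The pair of Gyg and Pygl in these lists is not a pair of paralogs and was tested as first written. A fall of respiration within the tumour cells themselves was not tested and stays open.

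NRF2 target genes were highest in tumour 6, where 15 of 18 genes of the list reached their highest value among the tumours; this list set the pattern and does not test it. The reference genes had a median excess of −0.0188 over the other tumours. The quantile step had already removed differences of scale, so this value cannot decide on the scaling of that array. A second list of NRF2 targets, written before its values were seen, had a median excess of 0.979 in tumour 6, with 14 of 16 genes highest there, and medians of −0.28 to 0.01 in the other tumours. These values are consistent with raised NRF2 activity in tumour 6, as a hypothesis found in a single tumour of these data.

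Of 792 possible splits of the 12 arrays into groups of 5 and 7, 100 were drawn with the real split among them. For genes higher, 1 split gave as many as the real 3506 (the real one itself, highest other 1942). For genes lower it was also 1 (real 2541, highest other 1920). For genes at least 2-fold higher 2 splits gave as many (real 666, highest other 672), and for genes at least 2-fold lower 1 (real 995, highest other 653). All of these lay under the bound of 5 in 100 splits set before the test. With 100 splits drawn no share below 1 in 100 can be shown, so chance is made unlikely but not excluded. The split with 672 set tumours 1, 3, 4, 6 and 7 against the normals with tumours 2 and 5, and so turned the real direction around.

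Among sex-linked genes, chosen after their values were seen, Eif2s3y of the Y chromosome had 8.19 in tumour 3 and 7.55 in tumour 5, against 9.53 to 10.56 on the other arrays. Kdm5d, also of the Y chromosome, had 6.70 in tumour 3 and 8.06 in tumour 5, against 7.31 to 7.74 on the other arrays. Uty, of the Y chromosome too, had 7.39 in tumour 3 and 7.68 in tumour 5, against 7.09 to 7.52, so the 3 genes did not go together. Xist had 7.17 in tumour 3, the highest of the arrays, and 6.90 in tumour 5, against 6.58 to 7.01 on the other arrays.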
